A study of Homo sapiens with 4 samples.

How the data were processed

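Gene expression was measured in 4 samples of H1, an established human embryonic stem cell line, on Affymetrix Exon 1.0 ST arrays, which carry short probes along the exons of each gene and summarise them as transcript clusters. Per the labels, the cells were grown in TESR medium on Matrigel, passaged with dispase and supplied as pellets in Trizol, and 1 ug of total RNA was labelled for each array. The labels give 1 group, H1_ES, with sample numbers 1 to 4 in the titles, and no control, treatment or second cell type. The titles of samples 1 and 2 are spelled in another form than those of samples 3 and 4, which was treated as a possible technical batch and not as a group of the study. Nothing in the sources states whether the 4 samples were separate cultures, so p-values measure only the spread between these samples, which may be technical.

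The deposited values are on a log2 scale, and per the submitters' processing notes Affymetrix Expression Console, RMA and the build hg18 were used; versions, the role of the build and the set of arrays normalized together are not given in the sources used here. The table held 22011 transcript clusters with values from 1.13 to 14.73, and no column of another sample. Column medians were 6.59, 6.79, 6.97 and 7.01 in samples 1 to 4, so the 4 columns did not share 1 distribution. Scanner files were not analysed here, so background correction, detection and saturation were not examined, and the number of arrays limits the precision.

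Gene names came from the platform annotation supplied with the values, matched by gene identifier to a RefSeq gene table of assembly GRCh38.p14. That assembly is not the build of the arrays, so none of its coordinates are printed; its gene spans and chromosomes served only as gene properties. There were 14432 transcript clusters with 1 gene symbol, 2408 with several and 5171 with none listed. Of those with 1 symbol, 14404 were found by gene identifier and 0 symbols needed an update. A transcript cluster with several symbols was not named. For a gene with several transcript clusters the one of highest mean was used, which left 14232 genes. POU5F1, NANOG and SOX2 occurred only in transcript clusters shared by several genes and TDGF1 had none of its own, so 15 of the 19 genes chosen to be always named are reported. Where a gene has close paralogs, as the histones, ribosomal protein genes and PMS2CL do, probes may also bind the paralogs and its values are uncertain.

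The group, the tests, 29 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The named genes are the always-named markers, the 10 genes of largest SD, for each sample the 5 genes of largest positive and the 5 of largest negative difference from the mean of the other 3, the genes of largest difference between samples 3 and 4 and samples 1 and 2, and up to 4 members of largest range in each list. Of the genes that this rule names for sample 1, all but 1 of those far above are reported here. Values are given as deposited. Signed differences are the named sample or pair minus the rest. Levels of different genes are not ranked against each other, because probes differ in affinity, and the planned description of list levels against random lists is therefore not reported.

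Tests used the 11006 transcript clusters whose mean over the 4 samples was at or above the median row mean of 6.84. Each sample was compared with the other 3, and each of the 3 splits into pairs was compared, with limma (version 3.58.1, R 4.3.3; lmFit, eBayes with trend) and Benjamini-Hochberg adjustment at an adjusted p of 0.05. These fits have 2 residual degrees of freedom, and a lone sample is assumed to vary like the others. In data simulated on these genes, with 100 genes changed at each size, the test recovered 44% of genes changed by 1 on the log2 scale and 99% of those changed by 2 for sample 1 against the rest. For samples 3 and 4 against samples 1 and 2 it recovered 62% and 100%. The simulated errors were independent and normal, with no offset between samples. For both comparisons their variances came from the limma fit of samples 3 and 4 against samples 1 and 2, and were already shrunk by it. Recovery in the real values can therefore be lower. In them SMU1 differed by -3.27 in sample 1 and did not pass. A count of 0 calls therefore does not show that no gene changed by 2. Gene lists were tested between samples 3 and 4 and samples 1 and 2 with camera, which asks whether a list moves relative to the other genes, with a preset inter-gene correlation of 0.01 and with an estimated one, for the 25 lists with at least 3 tested members. Medians of list levels can fall on different genes in different samples, so members were set against their own means before medians were taken, a step added after seeing the data. In single samples the median shift of a list was set against 10000 random lists of the same size matched on mean level, as a description and not a test. Unlike the tests, these shifts use all measured members of a list, also those under the filter on dim rows. Dixon's ratio, the gap of the farthest sample over the range, was computed per transcript cluster at its 95% critical value.

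The alternatives were quantile normalization, median centring, no filter or a stricter one at the 75th percentile, a floor at the 25th percentile (5.03), eBayes without trend, a range of 1.5, the mean over a gene's transcript clusters, an estimated correlation and leaving out each sample in turn. An estimated correlation without the filter, and random lists matched on gene span as well as mean level, were added as alternatives after seeing the data. The lists matched on span use coarser groups of mean level than those matched on mean level alone. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.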

Results

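RNA from 4 samples of the human embryonic stem cell line H1 was profiled on exon arrays to record the phenotype of each batch of cells grown by 1 supplier for the laboratories of a shared project. The labels describe the cells as karyotypically normal and 95% positive for Oct4. There was 1 group of 4 samples and no control, so levels were described and the samples were compared with each other.

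The pluripotency genes had similar levels in the 4 samples. The RNA-binding protein gene LIN28A had a log2 value of 12.93 ± 0.08 (SD, n = 4). The de novo DNA methyltransferase gene DNMT3B had 11.81 ± 0.21 (SD, n = 4), and the zinc finger gene ZFP42, also called REX1, had 11.13 ± 0.20 (SD, n = 4). Over the 22 measured members of the pluripotency list, each set against its own mean, the sample medians were -0.07, 0.04, 0.01 and 0.06. The median range of a member over the samples was 0.40, and 1 member, LIN28B, had a range of at least 1, with 8.09 in sample 1 and 9.51 in sample 4. The widest of the others among the list's named members were DPPA2 (range 0.77), PRDM14 (0.62) and L1TD1 (0.61). DPPA2 lay under the filter on dim rows and was not tested.

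As deposited, the named markers of differentiated lineages had ranges over the samples of 0.23 (SOX1) to 0.85 (AFP). The neural transcription factor genes PAX6 and SOX1 had log2 values of 4.46 ± 0.18 and 6.73 ± 0.11. The primitive streak genes TBXT and MIXL1 had 6.52 ± 0.16 and 7.15 ± 0.18. The endoderm genes SOX17, FOXA2 and GATA6 had 7.29 ± 0.23, 6.85 ± 0.20 and 7.37 ± 0.33, and alpha-fetoprotein (AFP) had 3.46 ± 0.36. The hormone subunit gene CGA and the transcription factor gene GATA3, both used as trophoblast markers, had 4.15 ± 0.26 and 5.72 ± 0.22. The mesenchymal matrix genes COL1A1 and LUM had 9.27 ± 0.24 and 3.21 ± 0.25 (SD, n = 4 throughout). After quantile normalization the ranges widened to 1.22 for GATA6, 1.16 for AFP, 0.90 for SOX17 and MIXL1 and 0.82 for FOXA2. They narrowed to 0.10 for TBXT, 0.25 for CGA and 0.30 for COL1A1. Sample 1 then lay above the other 3 by 1.00 for GATA6, 0.81 for SOX17, 0.72 for FOXA2 and 0.71 for MIXL1. How close the markers lie thus depends on the normalization. Without a control cell type, none of these values separates low expression from background signal.

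**Figure D1:**
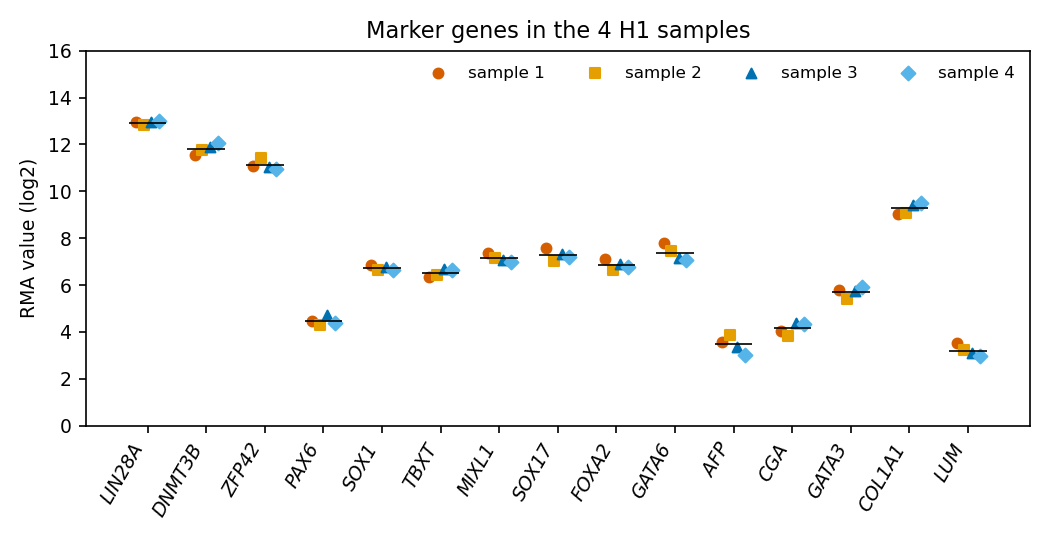
RMA values (log2, vertical axis) of 15 marker genes in the 4 H1 samples, with 1 symbol per sample and a black line at the mean of the 4. As deposited, the ranges of the genes run from 0.19 for LIN28A to 0.85 for AFP. After quantile normalization, not shown, they run from 0.10 for TBXT to 1.22 for GATA6. Levels of different genes are not comparable, because probes differ in affinity.

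For the other lists each member was also set against its own mean over the 4 samples, and the median member was taken in each sample. The SD of these 4 medians was 0.08 for the naive state list, 0.15 for primitive streak and mesoderm, 0.06 for definitive endoderm, 0.06 for neuroectoderm and 0.04 for neural crest. It was 0.24 for trophoblast and extraembryonic genes, 0.04 for hepatic and yolk sac genes, 0.12 for fibroblast and mesenchyme, 0.14 for endothelium and blood and 0.11 for germ cell genes. Single members moved more. CER1, a secreted antagonist of Nodal, had 6.43 in sample 2 and 4.78 in sample 3, and NODAL itself had 5.42 in sample 2 and 4.19 in sample 4. Both lay under the filter on dim rows and were not tested. COL1A2 had 8.89 and 9.20 in samples 1 and 2 and 10.03 and 10.10 in samples 3 and 4.

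Among signalling and stress lists, the same SD was 0.17 for Nodal and activin signalling, 0.15 for FGF and ERK feedback, 0.04 for immediate early genes, 0.14 for hypoxia and glycolysis, 0.11 for the ATF4 and amino acid response, 0.09 for ER chaperones, 0.18 for heat shock, 0.26 for p53 targets and 0.14 for the interferon response. For the metabolic and housekeeping lists it was 0.19 for cholesterol synthesis, 0.20 for oxidative phosphorylation, 0.16 for ribosomal proteins and 0.17 for replication-dependent histones. It was 0.26 for epithelial junctions and keratins, 0.39 for G2 and mitosis, 0.20 for DNA replication, 0.08 for imprinted genes and 0.16 for genes of a long-arm region of chromosome 20. The glycolytic enzyme gene PGK1 had 11.73 in sample 1 and 13.29 in sample 4. The death receptor gene FAS had 5.84 and 7.38, and the antiviral sensor gene RIGI had 5.28 and 6.72 in the same samples. The respiratory complex gene NDUFB3 had 5.55 in sample 2 and 3.57 in sample 4. RIGI and NDUFB3 lay under the filter on dim rows and were not tested.

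Samples 3 and 4 resembled each other most. Pearson's r across the 22011 transcript clusters, which are not independent replicates, was 0.992 for samples 3 and 4. It was 0.978 for samples 1 and 2, 0.970 for 1 and 3, 0.962 for 1 and 4, 0.980 for 2 and 3 and 0.979 for 2 and 4. The SD of the log2 differences was 0.300 between samples 3 and 4 and 0.635 between samples 1 and 4, the widest pair. Over the tested transcript clusters r fell to 0.935 for samples 1 and 4 and was 0.993 for samples 3 and 4.

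A range of at least 1, a difference of at least 2-fold between the highest and lowest sample, was found in 1880 of 11006 tested transcript clusters (17.1%). Sample 1 held the lowest value in 1706 of them, and sample 4 the highest in 1379. The 10 genes of largest SD all had their lowest value in sample 1. SMU1, a splicing factor gene, had log2 values of 5.27, 9.18, 7.98 and 8.46 in samples 1 to 4. The imprinted gene SNRPN, which encodes a small nuclear ribonucleoprotein, had 5.01, 7.19, 7.89 and 8.49. PNN, which encodes a nuclear speckle protein, had 7.52, 8.51, 9.92 and 10.26. The others were PMS2CL, ZNF483, TM9SF2, VAT1L, HTATSF1, LMAN1, which encodes a cargo receptor of the secretory pathway, and FUBP3, with SDs of 1.03 to 1.15. The count was 834 after quantile normalization and 319 without sample 1.

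**Figure D2:**
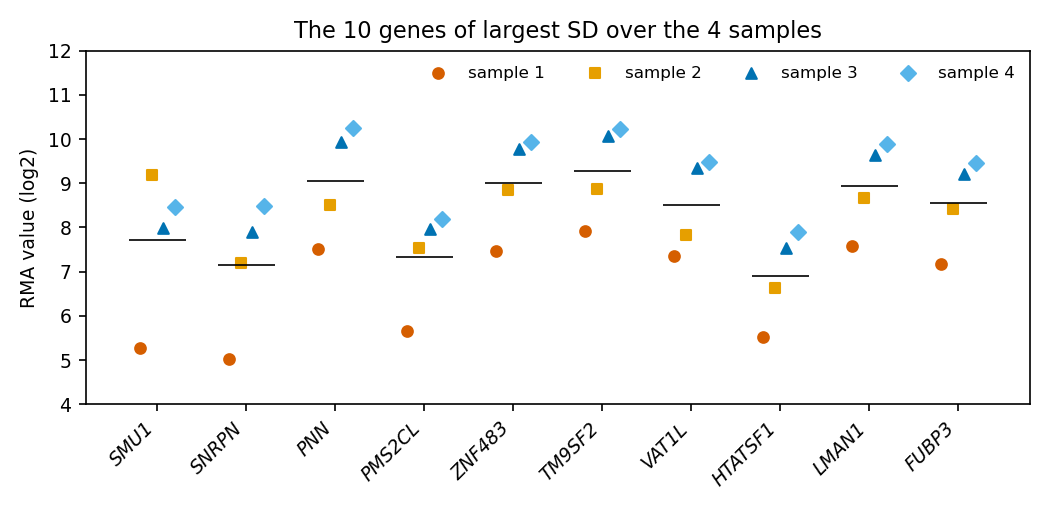
RMA values (log2, vertical axis, starting at 4) of the 10 genes of largest SD over the 4 samples, with 1 symbol per sample and a black line at the mean of the 4. Sample 1 is the lowest in each, at 5.27 for SMU1 and 5.01 for SNRPN.

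Sample 1 had lower values than the other 3 samples over most tested genes. Its median difference from their mean was -0.35 over the 11006 transcript clusters, and 925 lay at least 1 below that mean and 12 at least 1 above. The genes farthest below were SMU1 (-3.27), SNRPN (-2.84), PMS2CL (-2.24), PNN (-2.04) and ZNF483 (-2.04). The genes far above included KRTAP10-7 (1.32), the GABA transaminase gene ABAT (1.20), NLRP2 (1.13) and the melanopsin gene OPN4 (1.01). With limma, 0 transcript clusters passed the adjusted threshold and 4110 had an unadjusted p under 0.05; the smallest adjusted p was 0.0528. Leaving out sample 2 gave 6425 calls, sample 3 gave 518 and sample 4 gave 194, each with 1 residual degree of freedom. After quantile normalization the median difference was 0.01, and 236 transcript clusters lay at least 1 below and 73 at least 1 above.

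The G2 and mitosis genes, which drive chromosome segregation and cell division, were the list farthest below matched random lists in sample 1. Their median difference was -0.67, or -0.30 relative to random lists, and -0.34 relative to them after quantile normalization. The kinesin gene KIF11 had a difference of -1.47, CENPE -1.23, AURKA -1.07 and MKI67 -1.06. After quantile normalization these genes had -1.09, -0.96, -0.65 and -0.63. CENPE lay under the filter on dim rows and was not tested. With limma, 11 of 16 tested members passed when adjusted over the list alone and 0 passed over all transcript clusters. After quantile normalization 4 passed when adjusted over the list alone. The spread of a single sample is not measured and the list was picked out in these same samples, so these calls are not independent evidence. Relative to random lists, primitive streak genes lay higher in sample 1 by 0.34, immediate early genes by 0.32, definitive endoderm genes by 0.28, neural crest genes by 0.27 and pluripotency genes by 0.23. The lists include members under the filter on dim rows. Only 4 of 17 primitive streak, 4 of 13 definitive endoderm, 5 of 12 neural crest and 1 of 8 naive state genes passed it. Of the immediate early genes 15 of 17 passed it, and of the pluripotency genes 20 of 22. After quantile normalization the primitive streak and immediate early lists stayed outside the central 95% of random lists and the other 3 did not, while neuroectoderm genes, at 0.25 and inside it as deposited, lay outside it at 0.28. Set against random lists matched on gene span as well, the shifts of the primitive streak (0.20), immediate early (0.10), definitive endoderm (0.19) and neural crest (0.16) lists lay inside that interval, so these 4 shifts were not separated from gene span. The G2 and mitosis (-0.31), pluripotency (0.25) and naive state (0.34) lists lay outside it. Matched on mean level alone, 6 of 29 lists lay outside the interval in sample 1, where chance gives 1.45 in each sample, and 10 did so without sample 2. There were 6 such lists in sample 2, 7 in sample 3 and 8 in sample 4, and with span matched too there were 3, 6, 6 and 4 in samples 1 to 4.

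In sample 2, SMU1 (1.94), the dynein light chain gene DYNLL1 (1.31), RGS5 (1.20), the succinate dehydrogenase gene SDHC (1.16) and THOC7 (1.01) lay farthest above the other 3 samples. Without sample 1, SMU1 had 0.96 and SDHC 0.72. ANP32A (-1.19), GARS1 (-1.02), PTCRA (-0.95), PDCD5 (-0.94) and TMEM145 (-0.94) lay farthest below. Relative to random lists, oxidative phosphorylation genes lay higher by 0.35, cholesterol synthesis genes by 0.29, and the ATF4 and DNA replication lists by 0.16 each. Epithelial junction genes had -0.15 and trophoblast genes -0.24. With limma, 0 transcript clusters passed and 184 had an unadjusted p under 0.05; without sample 1, 1596 passed, with 1 residual degree of freedom.

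In samples 3 and 4, oxidative phosphorylation genes had -0.24 in each relative to random lists, immediate early genes -0.21 and -0.20, cholesterol synthesis genes -0.18 and -0.15, and the ATF4 list -0.14 and -0.17. G2 and mitosis genes had 0.18 and 0.32. Pluripotency genes had -0.10 and FGF and ERK feedback genes -0.12 in sample 3, and neural crest genes -0.29, definitive endoderm genes -0.22 and neuroectoderm genes -0.22 in sample 4. With span matched too, the definitive endoderm (-0.18), neuroectoderm (-0.16), cholesterol synthesis (-0.12) and immediate early (-0.09) lists of sample 4 and the FGF and ERK feedback list of sample 3 (-0.11) lay inside the central 95%. After quantile normalization the pluripotency list of sample 3 had -0.05 and lay inside it too. Each of the 2 samples counts in the mean that the other is compared with, so the shifts are not independent. In sample 3, PNN (1.16), VAT1L (1.13), H4C5 (1.08), CNMD (1.07) and TM9SF2 (1.07) lay farthest above the rest, and H2BC26 (-0.85), COX14 (-0.84), STMN3 (-0.84), PRR13 (-0.79) and TMEM98 (-0.74) farthest below. In sample 4, SNRPN (1.80), PNN (1.60), RPL35 (1.43), HTATSF1 (1.35) and ZNF143 (1.32) lay farthest above, and MAPK8IP2 (-0.87), OPN4 (-0.86), INAFM1 (-0.71), KRTCAP2 (-0.66) and TMEM98 (-0.62) farthest below. Without sample 1, CNMD had 0.66, VAT1L 0.69, PNN 0.54 and TM9SF2 0.53 in sample 3, and SNRPN 0.96, PNN 1.04, HTATSF1 0.82 and ZNF143 0.87 in sample 4. Without sample 3, TMEM98 had -0.98 in sample 4. With limma, 0 transcript clusters passed in either sample; 23 and 44 had an unadjusted p under 0.05. Leaving out sample 4 gave 17 calls for sample 3, and leaving out sample 3 gave 72 for sample 4.

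**Figure D3:**
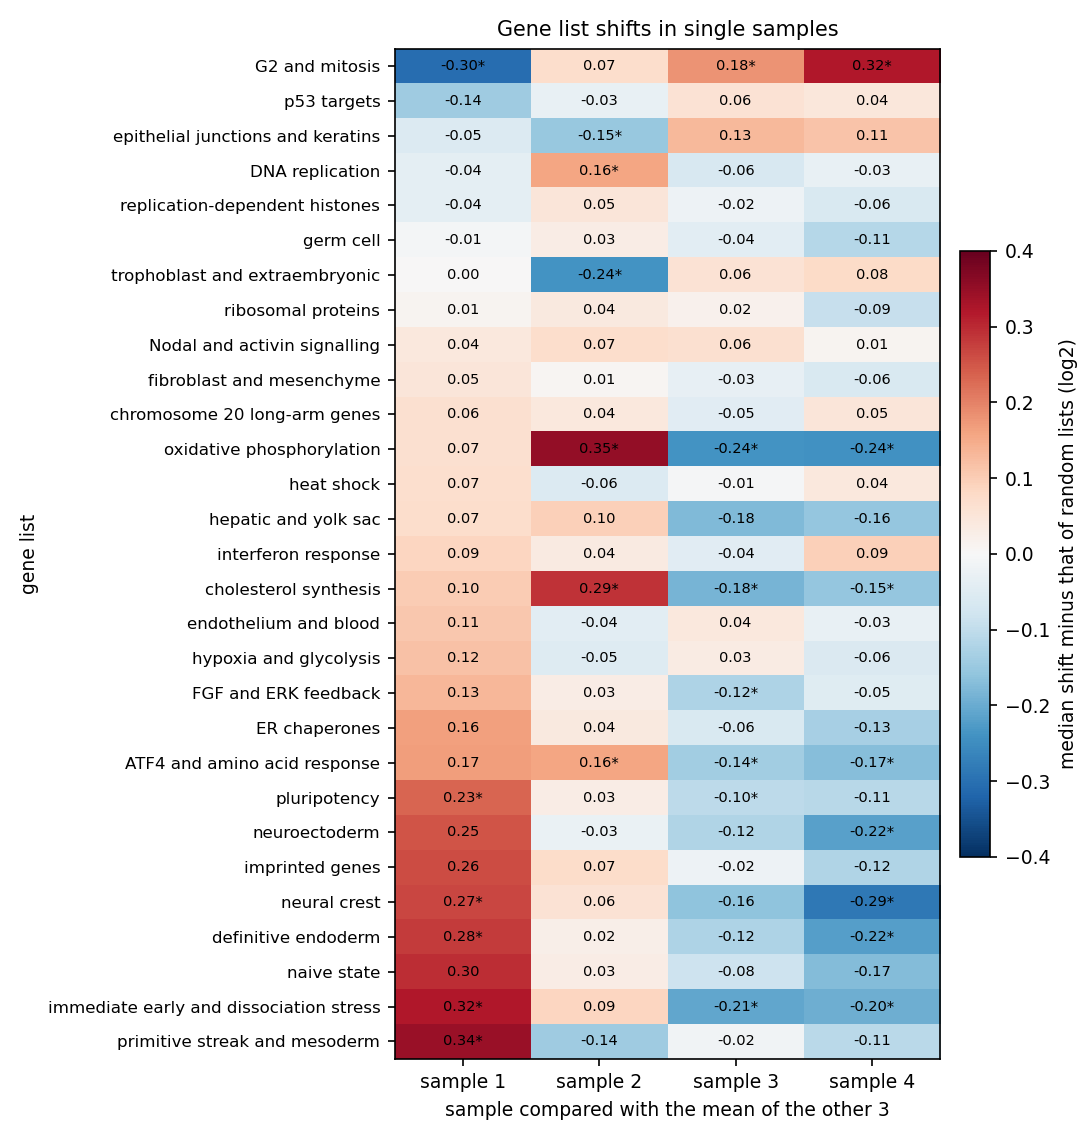
Median shift of 29 gene lists (rows) in each sample against the mean of the other 3 (columns), as log2 differences from random lists matched on mean level, with colour and printed values on the same scale. An asterisk marks a shift outside the central 95% of 10000 random lists; the G2 and mitosis list is at -0.30 in sample 1 and 0.32 in sample 4.

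Samples 3 and 4 were compared with samples 1 and 2 because the titles separate these pairs. The 5 genes of largest positive difference were SNRPN (2.09), PNN (2.07), VAT1L (1.82), TM9SF2 (1.76) and the chondromodulin gene CNMD (1.74). The 5 of largest negative difference were TMEM98 (-1.02), COX14 (-0.96), OPN4 (-0.84), PRR13 (-0.81) and YWHAH (-0.81). Without sample 1, SNRPN had 1.00 and OPN4 -0.49. The median difference over all tested transcript clusters was 0.26. With limma, 0 passed the adjusted threshold and 2607 had an unadjusted p under 0.05, with a smallest adjusted p of 0.132. After quantile normalization 126 passed, 84 higher and 42 lower in samples 3 and 4, among them CNMD and VAT1L with adjusted p = 0.036 and TMEM98 with 0.044. Leaving out 1 sample gave 17 to 6425 calls, the most without sample 2; these are the same fits as those of single samples above, because 1 sample then stands against 2. The other 2 splits into pairs gave 0 calls, with 107 and 8 transcript clusters at an unadjusted p under 0.05.

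Relative to the other genes, 4 of the 25 lists tested between these pairs passed with camera and a preset correlation, all lower in samples 3 and 4. None of the 4 passed with an estimated correlation (adjusted p = 0.98 each). That setting rests on the 2 residual degrees of freedom, and its smallest unadjusted p of all lists was 0.136. It could thus hardly pass any list and cannot decide on these 4. With the preset correlation, which is assumed, all 4 also passed after quantile normalization (adjusted p = 0.015, 0.018, 0.0077 and 0.018 in the order below). As deposited and with the preset correlation, oxidative phosphorylation genes had an adjusted p of 0.0011, with 2 of 12 members above the median gene. NDUFB5 had a difference of 0.15 and COX7B 0.09, but -0.09 and -0.18 after quantile normalization. The ATF4 and amino acid response list had an adjusted p of 0.0054, with 3 of 18 members above the median gene. The serine synthesis gene PSAT1 had -0.51, CTH -0.20 and the lipoprotein receptor gene VLDLR 0.88. After quantile normalization they had -0.61, -0.51 and 0.57. Cholesterol synthesis genes had an adjusted p of 0.0088, with 1 of 14 above the median gene. HMGCS1, which encodes an early enzyme of the pathway, had -0.29, IDI1 0.14, MVK 0.27 and NSDHL 0.53. After quantile normalization HMGCS1 had -0.50, IDI1 -0.17, MVK -0.03 and NSDHL 0.21. Immediate early genes had an adjusted p of 0.010, with 3 of 15 above the median gene. FOSL1 had -0.46, ATF3 0.39, KLF6 0.48 and IER2 0.71, and -0.80, 0.09, 0.17 and 0.40 after quantile normalization. These members were named for their range over the samples and not for their direction.

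The median difference of all tested genes was 0.27, so these lists differed from other genes more than from 0. The list medians were -0.14 for oxidative phosphorylation, -0.02 for ATF4, 0.01 for cholesterol synthesis and -0.05 for immediate early genes, and the means were -0.05, 0.02, 0.01 and 0.02. The test was thus negative where the mean was positive for 3 lists, and where the median was positive for cholesterol synthesis. Adjusted over the list alone, limma called 0 members of each of the 4 lists, as over all transcript clusters. After quantile normalization it called 6, 6, 5 and 0 members of the oxidative phosphorylation, ATF4, cholesterol and immediate early lists adjusted over the list alone, and 0 over all transcript clusters. The immediate early list did not pass without sample 1 (adjusted p = 0.178), and cholesterol synthesis did not pass without sample 2 (adjusted p = 0.204). The G2 and mitosis list, with 14 of 16 members above the median gene, had an adjusted p of 0.058 as deposited and 0.0077 after quantile normalization, and adjusted p = 0.98 with an estimated correlation. It was 0.205 without sample 1, 0.017 without sample 2, 0.026 without sample 3 and 0.025 without sample 4.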

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

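The tests of separate normalization, of other cells, of lost pluripotent cells and of dividing cells were chosen only after the result was seen. Because the study has 1 group, no biological explanation named by the design was tested.

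In 13 of the 188 values examined, 159 genes and 29 list medians, 1 sample lay apart from the other 3 by Dixon's ratio, where chance gives 9.4. Many of these genes, ABAT and NLRP2 among them, were named for a large difference or range, so this count is not a test. Sample 1 was the one apart in 10 of them and sample 2 in 3. Differences from the mean of the other 3 in sample 1 were 1.20 for ABAT, 0.86 for FOSL1 and 1.13 for NLRP2 above, and -1.10 for CCNE2, -0.59 for HERPUD1, -0.84 for HSPH1, -0.64 for KIT, -0.54 for MVK and -0.75 for SKIL below. The median tested transcript cluster already lay at -0.35 in sample 1. After quantile normalization those above grew to 1.62, 1.26 and 1.53. Those below shrank to -0.83 for CCNE2, -0.15 for HERPUD1, -0.45 for HSPH1, -0.19 for KIT, -0.20 for MVK and -0.33 for SKIL. The median level of the DNA replication list had -0.73, but these medians fall on different genes, and the median difference of its members was -0.39. In sample 2 the differences were 0.96 for BNIP3, 0.53 for HMGCS1 and 0.63 for SNAI2. CCNE2 and SNAI2 lay under the filter on dim rows and were not tested. Over the 11006 tested transcript clusters, 814 (7.40%) passed the same ratio, against a chance share of 5%, and 648 of them had sample 1 apart.

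The first pattern is the lower values of sample 1. Replacement of pluripotent cells was predicted to lower the pluripotency list by 1 or more on the log2 scale, and the list moved by 0.074 after quantile normalization. That bar was set after the result was seen and is larger than the median difference of -0.35. The value thus argues only against a loss large enough to lower the list by 1. The 95% bootstrap interval over members was -0.01 to 0.32. That interval does not measure the spread between samples, so the test cannot decide on replacement of a smaller share. The prediction for weaker signal from long genes was met. After quantile normalization, genes were cut into 5 equal groups by span. The longest group minus the shortest had median differences of -0.58 to -0.269 over 5 groups of mean level. Medians were -0.25 to -0.18 in the longest group and 0.08 to 0.33 in the shortest, so short genes lay higher too. The normalized median over all tested transcript clusters was 0.01, so this relation does not address the deposited median difference of -0.35. Span was not separated from base composition. An offset between columns could account for part, since 44.4% as many transcript clusters kept a range of at least 1 after quantile normalization. Other cell types cannot be told apart from these, with 2 of 8 lineage lists, primitive streak and neuroectoderm, above the central 95% of random lists after quantile normalization and both inside it as deposited with span matched too (97.3 and 90.6 percentile), and base composition was not tested.

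The second pattern is the lower G2 and mitosis list in sample 1. Long span is argued against, because among random lists matched on level and span the shift lay at the 0.16 percentile. Fewer dividing cells would lower the DNA replication list as well, and that list had a shift of -0.041 relative to random lists (35.9 percentile; 95% bootstrap interval -0.14 to 0.09). The criterion for that test was restated 2 times after its values were seen, each time more strictly and with the same outcome, but its margin is thin: the lists differed by 0.26, with an interval of 0.02 to 0.73. Both intervals treat list members as independent within 1 sample and do not measure the spread between samples. In the camera fit between the pairs, the estimated correlation of members was 0.82 for DNA replication and 0.89 for G2 and mitosis. The residuals of that fit include the difference between samples 1 and 2, so the estimates hold the shift of sample 1 itself. They do not give the size of any dependence between members. The intervals leave out any such dependence and can be too narrow, so the test cannot decide on fewer dividing cells. A different cell cycle distribution and base composition were not tested.

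The third pattern is in the exact values. Within samples 1 and 2, 235 transcript clusters had identical values, and within samples 3 and 4 there were 348, 583 in all, against 1 in the other 4 pairs. Samples 2 and 3 differed no more than samples 1 and 2 did (SD of differences 0.483 and 0.503). This is consistent with normalization of samples 1 and 2 apart from samples 3 and 4. If so, the comparison between these pairs cannot be separated from the normalization runs, and which arrays were normalized together is not stated.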

How the results depend on the processing

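The settings that join no filter with an estimated correlation, and that match random lists on gene span, were chosen after seeing the data. The count of transcript clusters with a range of at least 1 (1880) was 834 after quantile normalization, 896 after median centring, 4858 without a filter, 779 with the stricter filter, 417 at a range of 1.5 and 319 to 1785 when 1 sample was left out; the lowest was without sample 1. The filters change the number of transcript clusters examined and the range of 1.5 is a stricter rule; the cause of the others was not tested.

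With limma, calls stayed at 0 in all 7 comparisons under every setting that kept the 4 samples, except for 126 calls between samples 3 and 4 and samples 1 and 2 after quantile normalization. Leaving out 1 sample gave 194 to 6425 calls for sample 1 against the rest, 0 to 1596 for sample 2, 0 to 17 for sample 3, 0 to 72 for sample 4, 17 to 6425 for samples 3 and 4 against 1 and 2, 0 to 518 for samples 2 and 4 against 1 and 3, and 0 to 194 for samples 2 and 3 against 1 and 4. With 1 sample out, a split into pairs is the same fit as a comparison of a single sample, so these counts repeat each other. These fits keep 1 residual degree of freedom, and the residual is the difference between the 2 samples left together. The fits with the most calls rest on samples 3 and 4, the most alike pair. Its SD of differences over the tested transcript clusters was 0.16, against 0.36 to 0.52 in the other pairs. The counts thus depend on which pair sets the spread. For the lists, the settings with an estimated correlation could hardly pass any list, for the reason given above. Of 4 list calls, 0 passed with an estimated correlation and 0 with it and no filter; leaving out 1 sample gave 3 to 8 calls, 8 of them without sample 2. Lists apart in sample 1 (6) numbered 4 to 10 when 1 sample was left out, 10 without sample 2. With span matched too they numbered 3, and in sample 4 they numbered 4 instead of 8. The groups of mean level are then coarser as well, so the part due to gene span was not isolated.

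Pearson's r over the tested transcript clusters was 0.962 for samples 1 and 2, 0.946 for 1 and 3, 0.935 for 1 and 4, 0.967 for 2 and 3 and 0.968 for 2 and 4. The level of the imprinted list was 7.28 to 7.86 when 1 sample was left out, against 7.34 with all 4, highest without sample 1, where the middle gene is another one; the other 173 of 174 alternative list levels moved by less than 1 SD of medians. For the 50 differences for which genes were named, all 260 alternative values kept their direction and moved by less than 1 SD of the gene. Of these values, 18 of 160 changed by over 1.5 times when 1 sample was left out. The SD of a gene is over the same 4 values, and the genes were picked for large differences. For 1 sample against the rest, leaving out another sample cannot move a difference by 1 SD of the gene. Staying under 1 SD is therefore no sign that these differences are robust. Differences of other named genes were not among the 50, and some changed sign. After quantile normalization the difference between the pairs went from 0.14 to -0.17 for IDI1 and from 0.27 to -0.03 for MVK. It went from 0.15 to -0.09 for NDUFB5 and from 0.09 to -0.18 for COX7B. SNRPN between the pairs was 1.00 without sample 1 and 3.18 without sample 2, SMU1 in sample 2 was 0.96 without sample 1 and 2.55 without sample 4, and PNN and TM9SF2 in sample 3 were 0.54 and 0.53 without sample 1 and 1.91 and 1.68 without sample 4. No paired analysis was possible because the labels give 1 group, so no groups share replicate numbers. Signal over background was not examined, because scanner files were not used here.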

Other observations

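The chromosomes differed in sample 1 after quantile normalization. The median shift was -0.31 on chromosome 13 (134 genes), -0.24 on chromosome 18 and -0.17 on chromosome 10, and 0.21 on chromosome 19, 0.17 on chromosome 22 and 0.14 on chromosome 16. Across the 22 autosomes the shift went with the median gene span of the chromosome, with Spearman's rho of -0.797 and Pearson's r of -0.840 (permutation p = 0.0001 each, the smallest the permutations can give). Without the 2 chromosomes farthest from the median span, r was -0.736. This relation was the only one computed of its kind and was chosen after the shifts were seen; chromosomes were the units and the samples number 4.

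The first principal component of the tested values held 70.3% of the variance, with scores of -0.77, -0.11, 0.38 and 0.49 in samples 1 to 4. Samples 3 and 4 differed by at least 1 in 14 tested transcript clusters and samples 1 and 2 in 484.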
